A study of Mus musculus and Homo sapiens and Sus scrofa with 185 samples.

How the data were processed

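Bulk 3′ RNA sequencing was done on poly-A RNA with MARS-seq, a pooled barcoding method adapted by the authors to bulk samples, in which up to 8 samples were pooled before linear amplification. Per the labels, the authors used bcl2fastq, STAR 2.6.1 and DESeq2, named without their roles, and the builds mm10 and GRCm38 for mouse, GRCh38 for human and Sscrofa11.1 for pig. The deposited files are tables of raw read counts per gene and library, 1 per species, without normalization or transformation by the authors as far as the values show: all values were whole numbers. The counting tool, the strand setting and any use of molecular identifiers are not stated, so counts are treated as reads and intervals and floors cover counting error only. The total count per library ran from 0.53 M to 14.94 M in mouse, 3.04 M to 13.2 M in pig and 4.78 M to 54.87 M in human (M, mega).

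The mouse table used here was held in part: 38998 complete rows, with 1 incomplete row left out, covering 12 whole chromosomes and part of another. It holds 15763 of the 21951 protein-coding genes of the annotation (71.8%), and mouse totals and CPM (counts scaled to a common library size) refer to these rows. Genes on the other chromosomes, among them Cthrc1, Runx1, Sox9, Cd200, Col1a1 and Pecam1, were not analysed here. Mouse IDs were matched to symbols and positions with the GENCODE annotation of the GRCm38 build (38954 of 38998 matched) and human IDs with GENCODE release 44 (41885 of 58395 matched). The 25880 pig IDs were not paired with gene names in any file held, so pig results are given by ID, at most 2 in each direction for a comparison. From the human counts 511 sex-linked genes were removed before any test. Among the 387 pairs of libraries compared within groups, 0 had identical counts, and the lowest chi-square per degree of freedom was 2.86, so no library was taken for a repeat of another.

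Each library was assigned to its group and replicate from its title and labels. The series text places the knockout experiment at day 7 and the sample labels at day 5, and the labels were followed. Groups of an experiment and cell type, and all cell types of the knockout experiment, were fitted together with 1 estimate of spread. Genes were kept with filterByExpr by group, scaled by TMM and tested with edgeR 4.0.16 (estimateDisp, glmQLFit, glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. There were 40 tests: 35 pairs of groups, 1 of left against right ventricles as a mean over 3 conditions, and 4 of differences between effects. All of these, the first alternatives below, the gene lists and the rule for naming genes were fixed before the data were examined.

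The rule names, for each comparison, the gene the design is about, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean log2 CPM of at least 3, group ranges that do not overlap and an established symbol, and up to 4 members of each list with the lowest p. For the means and the tests of differences between effects the condition on ranges was not applied, and human clone names were treated like locus numbers. The 29 lists cover collagens, matricellular and other matrix proteins, collagen processing and crosslinking, contractile myofibroblast, TGF-β response, resting cardiac fibroblast, chondrocyte and osteoblast, Wnt pathway, cell cycle, interferon-stimulated, inflammatory cytokine, complement, class II antigen presentation, reparative macrophage, angiogenic endothelial, glycolysis and hypoxia, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, FOXO target, cardiac stress and dissociation genes, and markers of fibroblasts, endothelium, leukocytes, lymphocytes and neutrophils, pericytes and smooth muscle, cardiomyocytes, and epicardium, glia, adipocytes and erythroid cells. Lists with at least 5 tested members were tested with fry of limma 3.58.1, which asks whether the genes of a list move on balance one way and does not compare them with other genes, with adjustment over the lists of 1 comparison. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The class II list had 0 tested members in mouse. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over the group.

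The alternatives fixed in advance were RLE scaling, DESeq2 1.42.0 without independent filtering, no filter on low counts, the replicate number (or the donor, between ventricles) as a block, a fit of the 2 compared groups alone, each library left out in turn in groups of 2 to 5, a term for the format of the sample labels in human infarction, and healthy donors of the same label format in dilated cardiomyopathy. Leaving a library out of a group of 2 leaves 1, which is then assumed to vary like the other groups. Added after the data were seen was a term for 2 sets of GFP+ libraries, read from the first component of their residuals. So was the omission of 6 libraries whose mean correlation with their group lay more than 0.05 under its median. The last was the omission of 4 chromosome 21 genes in human. Whether replicate numbers pair libraries was checked by correlating residuals. Only day 14 against healthy GFP+ cells was taken as paired by number (r = 0.269 to 0.409). There 2 of 4 libraries matched best with their own number, and the check cannot tell pairing from the 2 library sets. Ventricles of a donor were taken as paired by their labels (6 of 6 healthy, 8 of 10 infarcted and 5 of 5 cardiomyopathy donors best with their own number). Pig zones at day 60 (5 of 6 best, lowest r = 0.026) were not. A block on the number elsewhere has no pairing shown behind it. Where at least 3 libraries stood on each side, up to 100 other splits of the same libraries were tested in the same way.

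The pipeline was tested on simulated data made from 6 comparisons, with known changes of 1.5-fold, 2-fold and 4-fold in up to 200 genes. Recovery with more genes changed was not tested. In GFP+ cells at day 7 it recovered 9.2%, 32.8% and 70.8% of them, with 7 false calls among 80. In the knockout fibroblasts it recovered 0%, 1.5% and 60%, in CD45+ cells at day 7 0% at each size, with Sox9 0%, 11.9% and 69.7%, in human infarcted left ventricle 3%, 30.3% and 84.1%, and in pig at day 180 52.2%, 80.6% and 98.5%. DESeq2 made more false calls on the same data than edgeR did: 22 of 110 calls against 7 of 80 in GFP+ cells, 19 of 81 against 2 of 42 in knockout fibroblasts, 26 of 47 against 0 of 0 in CD45+ cells, 19 of 92 against 6 of 60 with Sox9, 30 of 130 against 4 of 79 in human and 21 of 181 against 14 of 168 in pig. The limit on the share of false calls that this check allows was loosened once, after its first run. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Left out of every comparison were 3 cardiomyocyte libraries from day 5, which have no partner group.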

Results

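Gene expression was measured by bulk 3′ RNA sequencing in 185 libraries from 3 species: 105 from mouse, 38 from pig and 42 from human hearts. The mouse libraries came from cells sorted from hearts of a Col1a1-GFP reporter line, in which GFP marks collagen-producing cells, from CD31+ endothelial and CD45+ blood-derived cells of the same series, from GFP+ dermal fibroblasts, from knockout and wild-type hearts, and from cultured cardiac fibroblasts. GFP+ cardiac cells had 4 libraries each from healthy hearts, day 7 and day 14 after infarction and 2 from day 30. CD31+ cells had 4, 4, 2 and 4, and CD45+ cells 2, 4, 2 and 3, in the same order. Dermal fibroblasts, the infarct, border and remote zones at day 7, Cd200+ and Cd200− cells at day 7, and each cell type and genotype of the day 5 knockout experiment had 2 each. The cultures had 3 untransduced, 6 empty-vector, 6 Runx1 and 6 Sox9 lentivirus libraries, and 4 in each of 4 TGF-β1 arms. The pig libraries were 4 from healthy hearts, and 2, 6 and 9 each from the infarct and remote zones at days 8, 60 and 180. The human libraries were left and right ventricles of healthy donors (6 each), of hearts with myocardial infarction (10 each) and of hearts with dilated cardiomyopathy (5 each). Median total counts were 5.58 M (mega) per mouse library, 4.28 M in pig and 17.4 M in human. By group 7SL RNA genes took 7.01% to 9.67% and TTN 7.65% to 8.8% of human counts. A limit to 3′ poly-A reads was not tested. The mouse table used here held 71.8% of protein-coding genes, so its totals are those of part of each library. The labels do not say whether the replicates of a mouse or pig group came from separate animals or cultures.

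Values are log2 fold changes ± SE with Benjamini-Hochberg adjusted p from edgeR quasi-likelihood tests, and levels are mean CPM, counts scaled to a common library size, ± SD. Gene groups are lists fixed before the data were examined and tested for movement on balance in one direction with limma fry. For each list the members up and down among those tested come first, then the numbers adjusted over the list alone.

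In GFP+ cardiac fibroblasts 7 days after infarction, a comparison that opens the time course of the response to injury, secreted matrix genes rose. Postn (ENSMUSG00000027750, chromosome 3), the matricellular protein periostin, rose by 2.71 ± 0.42 (adjusted p 0.00276), from 687 ± 354 to 4509 ± 1877 CPM (n = 4 each). Tnc (tenascin C) rose by 3.78 ± 0.37, Fn1 (fibronectin) by 2.86 ± 0.37 and Spp1 (osteopontin) by 3.07 ± 0.45, with adjusted p up to 0.00222. Collagens rose on balance (6 of 14 up and 0 down, 9 and 0 adjusted over the list alone, fry adjusted p 2.18e-04), with Col1a2 at 1.59 ± 0.27, Col3a1 at 1.48 ± 0.25 and Col12a1 at 2.36 ± 0.38. So did matricellular and other matrix proteins (7 of 17 up and 1 down, 10 and 1 adjusted over the list alone, fry adjusted p 0.0019). Collagen processing genes moved the same way (5 of 14 up and 0 down, 5 and 0 adjusted over the list alone, fry adjusted p 0.0019), among them P4ha3, a collagen prolyl hydroxylase, at 4.56 ± 0.54. Secreted and target genes of the Wnt pathway moved up (4 of 10 up and 0 down, 7 and 0 adjusted over the list alone, fry adjusted p 0.00212), led by Sfrp2 at 3.12 ± 0.33. Cell cycle genes moved up (5 of 19 up and 0 down, 15 and 0 adjusted over the list alone, fry adjusted p 0.0147) with Tyms (thymidylate synthase) at 1.06 ± 0.21, a list call that ended in a fit of these groups alone (adjusted p 0.061). Interferon-stimulated genes moved up too (3 of 8 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 0.00604). Beside them, leukocyte markers summed to 392.6 ± 345 CPM at day 7 against 123.3 ± 112.6 in healthy hearts, a rise that fry did not call (adjusted p 0.303). Pericyte and smooth muscle markers summed to 399.5 ± 64.2 against 250.9 ± 19.6 CPM and cardiomyocyte markers to 254 ± 40.7 against 429.9 ± 38.1. Contractile myofibroblast genes did not pass as a group (3 of 11 up and 0 down, 6 and 0 adjusted over the list alone, fry adjusted p 0.108), though they did without day 7 replicate 3 (adjusted p 0.031). Neither TGF-β response genes (3 of 11 up and 1 down, 3 and 1 adjusted over the list alone, fry adjusted p 0.201) nor resting fibroblast genes (0 of 16 up and 0 down, 0 and 3 adjusted over the list alone, fry adjusted p 0.271) passed. Wt1, a transcription factor of the epicardium, rose by 6.80 ± 1.04 and Dmkn (dermokine) by 6.92 ± 0.87. The list of epicardial, glial, adipocyte and erythroid markers moved up (2 of 6 up and 0 down, 3 and 0 adjusted over the list alone, fry adjusted p 0.00393). Saa3, an acute-phase protein, rose by 4.84 ± 0.56 and the imprinted transcript H19 by 5.55 ± 0.54 (6.15 without healthy replicate 3). Prdx1 (peroxiredoxin 1) fell by 4.72 ± 0.93. Across 10743 genes tested, 731 passed (486 up and 245 down). The count was 178 and 256 without day 7 replicate 1 or 2, 447, 370 and 317 without healthy replicate 1, 3 or 4, 409 in a fit of these groups alone, and 1269 by DESeq2. A term for 2 library sets, read from the residuals after the data were seen, gave 1762. With it the contractile (adjusted p 0.0114), TGF-β response (0.0233) and leukocyte (0.022) lists passed, but it lowers the spread by construction.

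At day 14 the GFP+ cells were compared with healthy cells to follow the response into scar maturation. Sfrp2 was up by 4.02 ± 0.34 (adjusted p 2.78e-05). Genes best known from cartilage and tendon rose: Acan (aggrecan) rose by 4.10 ± 0.59 (5.18 without healthy replicate 3), Comp (cartilage oligomeric matrix protein) by 2.93 ± 0.47, Cilp by 1.82 ± 0.20 and Fmod (fibromodulin) by 1.42 ± 0.19, with adjusted p up to 0.00332. Chondrocyte and osteoblast genes rose as a list (4 of 7 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 2.55e-04). Collagens rose on balance (5 of 14 up and 0 down, 7 and 1 adjusted over the list alone, fry adjusted p 2.55e-04), with Col8a2 at 2.63 ± 0.22. Matricellular proteins did so too (10 of 17 up and 0 down, 11 and 1 adjusted over the list alone, fry adjusted p 2.55e-04), as did Wnt pathway genes (5 of 10 up and 1 down, 5 and 1 adjusted over the list alone, fry adjusted p 6.64e-04). Oxidative phosphorylation genes moved down (0 of 12 up and 1 down, 0 and 3 adjusted over the list alone, fry adjusted p 0.00407), with the complex I subunit Ndufs1 at -0.85 ± 0.13. Cell cycle genes did not move as a group (1 of 19 up and 0 down, 2 and 0 adjusted over the list alone, fry adjusted p 0.901), with a mean of -0.41 although fry pointed up. Cd34, a surface marker of resting fibroblasts, fell by 0.92 ± 0.16. Beside these lists, endothelial markers summed to 519.7 ± 88.8 CPM against 886.4 ± 250 in healthy hearts. In all 441 genes passed (300 up, 141 down), and chance was not excluded for that count. The count was 272 and 268 without healthy replicate 1 or 4, 293 and 245 without day 14 replicate 3 or 4, 224 in a fit of these groups alone, 867 by DESeq2 and 1311 with a term for the library set. Replicate numbers were taken as paired, with 2 of 4 libraries best with their own number, and a fit blocked on the replicate gave 300.

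At day 30, the latest time in mouse, 76 genes passed (63 up, 13 down, n = 2 against 4). Sfrp2 stood at 3.62 ± 0.36 (adjusted p 1.78e-04). Tnmd (tenomodulin, a tendon protein) rose by 3.59 ± 0.40, Angptl7 by 2.64 ± 0.25, Cilp by 2.14 ± 0.23 and Fmod by 1.84 ± 0.22, with adjusted p up to 9.47e-04. Chondrocyte and osteoblast genes were up as a group (2 of 7 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 0.00148). Matricellular proteins were up (5 of 17 up and 0 down, 8 and 1 adjusted over the list alone, fry adjusted p 0.00611), as were Wnt pathway genes (3 of 10 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 0.00611). Collagens were up (1 of 14 up and 0 down, 2 and 0 adjusted over the list alone, fry adjusted p 0.0133), a call that ended without day 30 replicate 2 (adjusted p 0.0615), blocked on the replicate and in a fit of these groups alone. Endothelial markers summed to 578.3 ± 27.9 CPM against 886.4 ± 250 in healthy hearts. The count of genes was 48, 42 and 46 without healthy replicate 1, 3 or 4, and 30 blocked on the replicate. It was 273 by DESeq2 and 396 with a term for the library set. No test compared the times with each other.

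**Figure D1:**
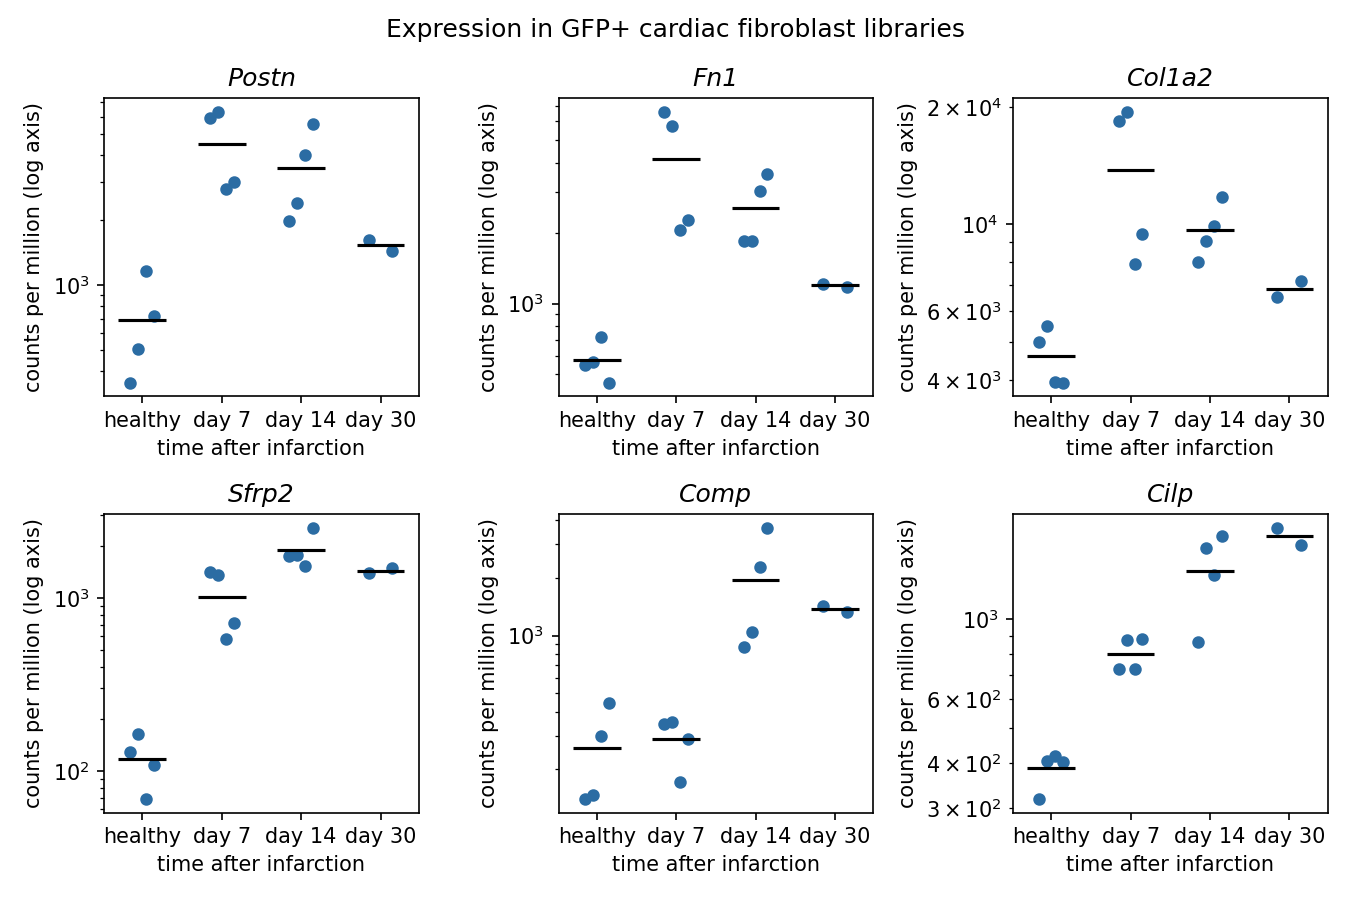
CPM on a log axis for 6 genes in each GFP+ library of healthy hearts and of days 7, 14 and 30 after infarction. Points are libraries (n = 4, 4, 4 and 2) and bars are group means. The means of Postn and Fn1 were highest at day 7, that of Comp at day 14 and that of Cilp at day 30.

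In CD31+ endothelial cells the comparison asked how the endothelium responded over the same course. At day 7, 3 genes passed, all up. Arg1 (arginase 1, abundant in reparative macrophages) reached 52.8 CPM, at least 419-fold above healthy cells, in which it had 0 counts (268-fold without healthy replicate 2). The mitotic genes Knstrn and Cenpa, named because the count was small and after their values were seen, rose by 2.94 ± 0.48 and 1.52 ± 0.24. Cell cycle genes moved up as a group (0 of 19 up and 0 down, 16 and 0 adjusted over the list alone, fry adjusted p 0.00159) and endothelial markers moved down (0 of 12 up and 0 down, 0 and 2 adjusted over the list alone, fry adjusted p 0.00159). Leukocyte markers summed to 2876 ± 1971 CPM against 546.8 ± 572.8 in healthy cells. At unadjusted p below 0.05 there were 911 genes. The 3 calls became 0 without day 7 replicate 1, 2 or 4, without any 1 healthy replicate and blocked on the replicate, 2 without day 7 replicate 3 (Knstrn and Cenpa not among them), 19 in a fit of these groups alone, 80 with no filter and 113 by DESeq2. At day 14, 279 genes passed (147 up, 132 down). Among them were the respiratory chain gene Cox7a2 at 2.35 ± 0.44 and the mitochondrial ribosome gene Mrps21 at 2.42 ± 0.44, while Mgst1, a glutathione transferase, fell by 2.04 ± 0.35. Each of these 3 calls ended without day 14 replicate 2 (adjusted p 0.102, 0.0891 and 0.111). Cardiac stress genes moved up (1 of 7 up and 0 down, 3 and 0 adjusted over the list alone, fry adjusted p 3.27e-04). In the same libraries lymphocyte and neutrophil markers summed to 105.4 ± 27 CPM against 9.497 ± 5.56 in healthy cells and endothelial markers to 92350 ± 11240 against 59620 ± 13000. That count was 129, 127 and 98 without healthy replicate 1, 2 or 4, and 54 blocked on the replicate. It was 143 in a fit of these groups alone and 837 by DESeq2. At day 30, 0 genes passed by edgeR, with 606 at unadjusted p below 0.05, 11 by DESeq2 and 9 with no filter. Interferon-stimulated genes moved down as a group there (0 of 8 up and 0 down, 0 and 1 adjusted over the list alone, fry adjusted p 5.96e-04).

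In CD45+ cells, compared over the same days, Arg1 passed at day 7, rising by 6.31 ± 0.75 (adjusted p 0.016) from 6.77 ± 3.37 to 543 ± 312 CPM. It was the 1 call by edgeR, with 657 genes at unadjusted p below 0.05. FOXO targets (0 of 11 up and 0 down, 0 and 4 adjusted over the list alone, fry adjusted p 0.0316) and immediate early genes of the kind induced by tissue dissociation (0 of 8 up and 0 down, 0 and 1 adjusted over the list alone, fry adjusted p 0.0316) moved down. Both list calls ended without day 7 replicate 2, 3 or 4 or either healthy replicate (adjusted p 0.0676 to 0.344), with no filter (0.0628) and in a fit of these groups alone (0.21 and 0.142). That of FOXO targets also ended without day 7 replicate 1 (0.0715), and the mean of that list went from -0.53 to 0.09 without healthy replicate 1. The day 7 libraries stood in 2 pairs, replicates 1 and 2 with 12473 and 12567 genes detected and replicates 3 and 4 with 9542 and 9585, and correlated at r = 0.713 to 0.797. Their leukocyte markers summed to 45610 ± 23380 CPM against 54040 ± 7359 in healthy hearts, cardiomyocyte markers to 275.3 ± 115 against 551.2 ± 70.7, and epicardial, glial, adipocyte and erythroid markers to 226.9 ± 336 against 8.806 ± 0.644. The Arg1 call ended without healthy replicate 1 or 2 (0 genes each) and in a fit of these groups alone (0). The count was 2 without day 7 replicate 2 or 4, 25 blocked on the replicate, 117 with no filter and 92 by DESeq2. At days 14 and 30, 0 genes passed by edgeR, with 396 and 412 at unadjusted p below 0.05, 11 and 18 by DESeq2, and 17 and 127 with no filter. Blocked on the replicate, day 30 gave 3. At day 14 the neutrophil gene S100a8 stood at 3.66 ± 0.88 and Arg1 at 3.53 ± 0.69, short of the threshold by edgeR. They passed with no filter and by DESeq2, which in CD45+ data simulated at day 7 made 47 calls of which 26 were false. Without day 14 replicate 2 the count was 2, S100a8 among them (adjusted p 0.0105). Of changes simulated at 2-fold and 4-fold in CD45+ cells at day 7, edgeR recovered 0%.

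Dermal fibroblasts, sorted at day 30 as fibroblasts from outside the heart, gave 0 genes by edgeR, 471 at unadjusted p below 0.05 and 9 by DESeq2. The 2 day 30 libraries correlated at r = 0.574, and replicate 2 held 0.72 M counts and 5925 genes where replicate 1 held 5.6 M and 11398. The count was 5237 without day 30 replicate 1, 555 without replicate 2, and 8 and 13 without healthy replicate 1 or 2, so the result rested on single libraries. It was 56 with no filter and 11 blocked on the replicate. The leukocyte markers came to 7132 ± 1548 CPM in healthy and 6280 ± 1165 CPM in day 30 dermal libraries. No list moved, with collagens and immediate early genes nearest at the same adjusted p (for the latter 0 of 8 rose and 0 fell (0 and 2 adjusted over the list alone), mean -0.90, adjusted p 0.0855). Fibroblast markers summed to 44020 ± 10010 CPM at day 30 and 77980 ± 14570 in healthy libraries, cardiomyocyte markers to 2691 ± 3173 and 219 ± 36.6, and pericyte and smooth muscle markers to 803.1 ± 916 and 312.3 ± 1.02.

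At day 7 the infarct, border and remote zones were sorted for GFP+ cells to place the response within the heart. In the infarct zone Fn1 was up by 3.55 ± 0.24 against the remote zone, Postn by 2.89 ± 0.23, Tnc by 4.38 ± 0.43 and Col11a1 by 6.21 ± 0.65, with adjusted p up to 3.17e-06 (n = 2 each). Tnc stood at 3.75 and 5.41 without remote replicate 1 or 2 and Col11a1 at 5.31 without replicate 2, while without replicate 1 the other remote library had 0 counts of Col11a1. Of the resting fibroblast genes 0 of 16 tested genes rose, 14 fell and 2 did not pass (0 rose and 15 fell adjusted over the list alone) (fry adjusted p 9.25e-04). Among them were Inmt, a methyltransferase, at -2.94 ± 0.27, Gsn (gelsolin) at -1.81 ± 0.23 and the scavenger receptor Scara5 at -1.91 ± 0.25. Matricellular proteins (11 of 17 up and 1 down, 12 and 1 adjusted over the list alone, fry adjusted p 0.00895) and collagens (9 of 14 up and 0 down, 9 and 1 adjusted over the list alone, fry adjusted p 0.022) rose on balance. TGF-β response genes (4 of 11 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 0.00483) and contractile genes (4 of 11 up and 0 down, 7 and 0 adjusted over the list alone, fry adjusted p 0.0212) rose too, with Tagln (transgelin) at 2.14 ± 0.26 and Palld (palladin) at 3.49 ± 0.28. Pericyte and smooth muscle markers moved up (5 of 8 up and 0 down, 7 and 0 adjusted over the list alone, fry adjusted p 0.00895), with Rgs5 at 2.83 ± 0.29. These 5 list calls ended without remote replicate 1 or 2 (adjusted p 0.109 to 0.201), and that of contractile genes in a fit of these groups alone (0.0546). That of collagens also ended without infarct replicate 1 (0.0678) or 2 (0.0947) and blocked on the replicate (0.0634). Leukocyte markers summed to 1027 ± 1192 CPM in the infarct zone, 231.4 ± 29.9 in the border zone and 13.86 ± 3.91 in the remote zone. Beside the matrix genes 8 of 12 leukocyte markers rose, with Lyz2 at 8.80 ± 0.96 and Tyrobp at 6.79 ± 0.95. Infarct replicate 1, with 0.53 M counts, held 1869 CPM of leukocyte markers and replicate 2, with 5.91 M, held 184. Without infarct replicate 1 or 2 Lyz2 stood at 6.48 and 9.72 and Tyrobp at 4.40 and 7.80. Without remote replicate 2 they stood at 7.90 and 5.88, and without remote replicate 1 the other remote library had 0 counts of both. Fry did not call that list (adjusted p 0.113) but did without infarct replicate 1 (0.0166) or 2 (0.0143). Chil3 was at least 110-fold and Arg1 at least 177-fold above the remote zone. Without infarct replicate 1 or 2 the bound on Arg1 was 41.6-fold and 312-fold, and without remote replicate 1 or 2 it was 82.1-fold and 94.6-fold, with 51.3-fold and 59.1-fold for Chil3. Inflammatory cytokines did not move on balance (3 of 9 up and 1 down, 3 and 4 adjusted over the list alone, fry adjusted p 0.86), with a mean of 0.98 although fry pointed down. Here 478 genes passed (288 up, 190 down) and 760 in a fit of these groups alone.

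In the border zone 347 genes passed (207 up, 140 down). Postn was up by 2.08 ± 0.22, Tnc by 2.49 ± 0.41 and Fn1 by 1.59 ± 0.22. Resting fibroblast genes moved down against the remote zone (0 of 16 up and 2 down, 0 and 5 adjusted over the list alone, fry adjusted p 0.0151). Beside them endothelial markers summed to 954.4 ± 107 CPM in the border and 491 ± 28 in the remote zone, and pericyte and smooth muscle markers to 352.7 ± 43.2 and 161.2 ± 16, where the latter moved up as a list (2 of 8 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 0.0343). Wnt pathway genes moved down (0 of 10 up and 4 down, 2 and 5 adjusted over the list alone, fry adjusted p 0.0343), with the Wnt inhibitor Wif1 at -6.03 ± 0.62 (-5.23 without border replicate 1, while without replicate 2 the border zone kept 1 count). Tnc stood at 1.85 and 3.51 without remote replicate 1 or 2. These 3 list calls ended without any 1 of the 4 libraries (adjusted p 0.091 to 0.239). Those of Wnt pathway genes and pericyte markers also ended with no filter, blocked on the replicate and in a fit of these groups alone (0.0636 to 0.0931). The count of genes was 131 and 174 without remote replicate 1 or 2 and 580 without border replicate 2.

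**Figure D2:**
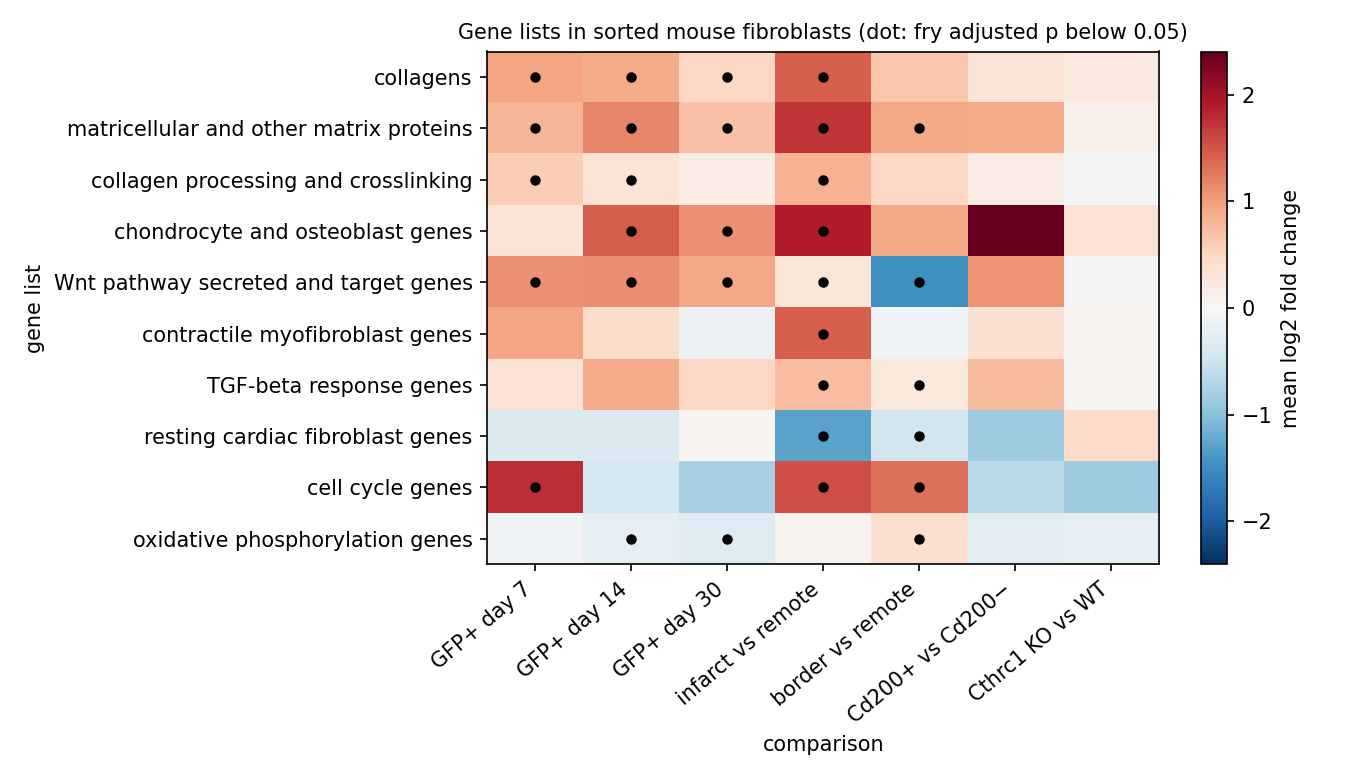
Mean log2 fold change of the tested members of 10 fixed gene lists (rows) in 7 comparisons of sorted mouse cells (columns). Dots mark lists with a fry adjusted p below 0.05. Collagens and matricellular proteins were above 0 with a dot at days 7, 14 and 30 in GFP+ fibroblasts and in the infarct zone.

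Cd200+ and Cd200− fibroblasts at day 7, both sorted as Cd146−, served to compare surface-marker subsets. The sort gene Cd200 was not analysed here, and Mcam, which encodes the Cd146 of the gate, stood at -0.13 ± 0.89 (adjusted p 0.961). Cd200+ cells held more of the cartilage and tendon matrix genes Comp (3.66 ± 0.30), Fmod (3.88 ± 0.37) and Cilp2 (5.82 ± 0.78), with adjusted p up to 0.0127. Cilp2 stood at 4.77 without Cd200− replicate 2, and without replicate 1 the other Cd200− library had 0 counts. The chondrocyte and osteoblast list did not pass (3 of 7 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 0.12). Upk3b, a mesothelial membrane protein, was up by 6.39 ± 0.44. Hsd11b1, which regenerates active glucocorticoid, was down at -3.71 ± 0.43, Lpl (lipoprotein lipase) at -1.68 ± 0.32 and the alcohol dehydrogenase Adh1 at -2.93 ± 0.49. Adh1 stood at -2.32 and -3.90 without Cd200+ replicate 1 or 2, and Hsd11b1 at -4.49 without replicate 2. Resting fibroblast genes did not pass (0 of 16 up and 3 down, 0 and 6 adjusted over the list alone, fry adjusted p 0.251). Leukocyte markers summed to 18.41 ± 5.89 CPM in Cd200+ and 77.63 ± 30.8 in Cd200− cells and did not pass either (0 of 8 up and 0 down, 0 and 3 adjusted over the list alone, fry adjusted p 0.196). Pericyte and smooth muscle markers summed to 154.5 ± 14.5 and 63.33 ± 1.89 CPM in the same order and did not pass (1 of 8 up and 0 down, 4 and 1 adjusted over the list alone, fry adjusted p 0.107). Of 9076 genes 69 passed (41 up, 28 down). The count was 729 blocked on the replicate (pairing not decided), 412 with no filter and 316 by DESeq2.

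Cultured cardiac fibroblasts were transduced with Runx1, Sox9 or empty lentivirus to ask what either transcription factor does when supplied. Runx1 and Sox9 themselves were not analysed here. With Runx1, Loxl3, a collagen crosslinking oxidase, rose by 1.85 ± 0.21 (adjusted p 1.6e-04), Gnao1, a G protein subunit, by 2.33 ± 0.28 and Serpinf1, an antiangiogenic serpin, by 2.01 ± 0.34 (n = 6 each). Asic3, an acid-sensing ion channel, rose by 4.02 ± 0.55 and Hsd11b1 fell by 1.63 ± 0.26, with adjusted p up to 0.00614. No list passed, with pericyte markers nearest (0 of 5 up and 0 down, 1 and 0 adjusted over the list alone, fry adjusted p 0.07). Among resting fibroblast genes 3 of 14 fell (fry adjusted p 0.296). Of 10195 genes 225 passed, 49 up and 176 down, a number that chance was not excluded for. The count was 112 by DESeq2, 387 with no filter, 12 blocked on the replicate and 42 in a fit of these groups alone. It was 52 without the libraries of low agreement, empty vector replicate 1 and Runx1 replicate 5, an alternative added after the data were seen.

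Sox9 changed 2259 genes (1054 up, 1205 down), and no alternative that was run moved that count by more than 1.5 times. Sox9 replicates 1, 3 and 4 stood apart with 10101, 10524 and 11082 genes detected, against 13366 to 14014 in the other Sox9 and 12527 to 14411 in the empty-vector libraries. Their scaling factors were 0.79 to 0.82, against 0.97 to 0.99 in the other Sox9 libraries. Without these 3, left out after the data were seen, Lum below stood at 4.58, Actg2 at -4.1 and Tagln at -2.46. Saa3 rose by 9.78 ± 0.76, Lcn2 (lipocalin 2) by 7.57 ± 0.67, the matrix metalloproteinase Mmp3 by 6.52 ± 1.16 and the cytokine Il6 by 5.22 ± 0.81, with adjusted p up to 6.61e-04. Resting fibroblast genes moved up (8 of 14 up and 0 down, 10 and 0 adjusted over the list alone, fry adjusted p 0.00319), as did fibroblast markers (8 of 11 up and 0 down, 9 and 1 adjusted over the list alone, fry adjusted p 6.76e-04), with the proteoglycans Dcn at 5.09 ± 0.70 and Lum at 5.80 ± 0.93. Complement genes moved up (3 of 5 up and 0 down, 5 and 0 adjusted over the list alone, fry adjusted p 1.31e-04). Cholesterol synthesis genes moved up together (8 of 12 up and 0 down, 10 and 0 adjusted over the list alone, fry adjusted p 3.77e-06). Of the chondrocyte and osteoblast genes, the field in which Sox9 is best known, 2 of 5 tested genes rose, 0 fell and 3 did not pass (2 rose and 0 fell adjusted over the list alone) (fry adjusted p 7.99e-04). Contractile genes moved down (0 of 11 up and 7 down, 0 and 9 adjusted over the list alone, fry adjusted p 8.93e-04), with Actg2 at -4.79 ± 0.81 and Tagln at -1.81 ± 0.36. Cell cycle genes moved down (0 of 19 up and 15 down, 0 and 17 adjusted over the list alone, fry adjusted p 7.78e-08), with the replication helicase subunit Mcm5 at -1.71 ± 0.20. Glycolysis and hypoxia genes moved up (3 of 13 up and 0 down, 3 and 0 adjusted over the list alone, fry adjusted p 0.00319), and collagens did not pass (3 of 13 up and 0 down, 3 and 0 adjusted over the list alone, fry adjusted p 0.269) except in a fit of these groups alone (adjusted p 0.0425). Leukocyte markers summed to 106.8 ± 41.9 CPM with Sox9 and 42.39 ± 6.3 with empty vector, and pericyte and smooth muscle markers to 32.35 ± 5.65 and 52.16 ± 9.9.

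Empty lentivirus against untransduced cells served as the control for transduction. Between these groups 190 genes passed (91 up, 99 down, n = 6 against 3), a count for which chance was not excluded. The galectin Lgals3 rose by 2.93 ± 0.53 and Rragd, of the nutrient-sensing Rag complex, by 4.31 ± 0.57, with adjusted p up to 0.00756. Collagens moved down (0 of 13 up and 2 down, 0 and 7 adjusted over the list alone, fry adjusted p 0.0402), as did collagen processing genes (0 of 14 up and 1 down, 0 and 9 adjusted over the list alone, fry adjusted p 0.0402). Endothelial markers summed to 1120 ± 169 CPM with empty vector and 728.7 ± 157 without. Both list calls ended without untransduced replicate 3 (adjusted p 0.124 and 0.219), with no filter, blocked on the replicate and in a fit of these groups alone. The count of genes was 109, 95 and 44 without untransduced replicate 1, 2 or 3, 25 blocked on the replicate, 71 with no filter, 434 by DESeq2 and 557 in a fit of these groups alone. It was 581 without the library of low agreement, empty vector replicate 1.

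TGF-β1 (10 ng/mL, 48 h), the cytokine that drives fibroblasts towards myofibroblasts, changed 3836 of 8962 genes (1833 up, 2003 down, n = 4 each). Of the contractile myofibroblast genes 10 of 11 tested genes rose, 0 fell and 1 did not pass (10 rose and 0 fell adjusted over the list alone) (fry adjusted p 1.96e-10). Acta1 stood at 7.03 ± 0.70, Cnn1 (calponin) at 5.60 ± 0.33, Tagln at 3.27 ± 0.18 and Tpm1 (tropomyosin) at 2.91 ± 0.12, with adjusted p up to 8.31e-07. Without control replicate 2 the other control libraries had 0 counts of Acta1. TGF-β response genes rose (10 of 11 up and 0 down, 10 and 0 adjusted over the list alone, fry adjusted p 2.83e-11), among them Ccn2 at 2.90 ± 0.33. Cholesterol synthesis genes moved up (11 of 12 up and 0 down, 11 and 0 adjusted over the list alone, fry adjusted p 4.09e-10), with Lss, of the sterol pathway, at 2.11 ± 0.16. Glycolysis genes moved up as well (9 of 13 up and 0 down, 9 and 0 adjusted over the list alone, fry adjusted p 1.79e-05). Resting fibroblast genes fell (0 of 15 up and 13 down, 0 and 14 adjusted over the list alone, fry adjusted p 6.01e-12), with Scara5 at -5.99 ± 0.44 and the fibroblast receptor Pdgfra at -2.30 ± 0.19. FOXO targets moved down (0 of 12 up and 11 down, 0 and 11 adjusted over the list alone, fry adjusted p 2.98e-10), as did fatty acid oxidation genes (2 of 15 up and 6 down, 2 and 6 adjusted over the list alone, fry adjusted p 1.76e-05). Collagens went both ways (4 of 14 up and 6 down, 4 and 6 adjusted over the list alone, fry adjusted p 0.134): Col8a2 rose by 2.84 ± 0.44 and Col5a3 fell by 2.35 ± 0.19. Their median was -0.30 and their mean 0.00, and fry pointed down. Eln (elastin) was up by 3.21 ± 0.21 and the chemokine Cxcl5 down at -6.97 ± 0.56. Leukocyte markers fell from 1360 ± 268 to 601.5 ± 72.9 CPM (0 of 12 up and 11 down, 0 and 11 adjusted over the list alone, fry adjusted p 2.92e-07), beside a fall of reparative macrophage genes (1 of 11 up and 7 down, 1 and 7 adjusted over the list alone, fry adjusted p 1.78e-06). Pericyte and smooth muscle markers summed to 84.82 ± 30.1 CPM with TGF-β1 and 21.55 ± 0.892 without, fibroblast markers to 17120 ± 4969 and 27390 ± 3016, and cardiomyocyte markers to 409.5 ± 25 and 233 ± 20.7.

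LY294002 (40 µM), an inhibitor of PI3K, was added to TGF-β1 and compared with TGF-β1 and DMSO, its vehicle, to ask how far the response needs that pathway. It changed 4418 genes (2089 up, 2329 down, n = 4 each). Collagens moved down on balance (0 of 14 up and 11 down, 0 and 13 adjusted over the list alone, fry adjusted p 4.57e-09), with Col3a1 at -4.21 ± 0.49 and Col1a2 at -2.42 ± 0.20. Matricellular proteins moved down (2 of 17 up and 13 down, 2 and 14 adjusted over the list alone, fry adjusted p 1.17e-12), as did contractile genes (0 of 11 up and 8 down, 0 and 9 adjusted over the list alone, fry adjusted p 1.9e-09), with Eln at -4.97 ± 0.23, Cilp at -4.95 ± 0.23 and Cnn1 at -6.01 ± 0.35. Of the cholesterol synthesis genes 0 of 12 tested genes rose, 12 fell and 0 did not pass (0 rose and 12 fell adjusted over the list alone) (mean -3.26, fry adjusted p 4.71e-13). Lss was at -4.90 ± 0.19. FOXO targets moved up (6 of 12 up and 3 down, 6 and 3 adjusted over the list alone, fry adjusted p 4.23e-06), with the insulin pathway gene Irs2 at 2.37 ± 0.16. The pro-apoptotic Bcl2l11, not on that list, stood at 2.94 ± 0.24. TGF-β response genes moved up on balance (4 of 11 up and 1 down, 4 and 1 adjusted over the list alone, fry adjusted p 8.62e-07), with Timp1 at 3.36 ± 0.22. The cytokine Il11 rose by 6.03 ± 0.57. Fibroblast markers summed to 5800 ± 205 CPM with LY294002 and 15980 ± 2001 with DMSO, cardiomyocyte markers to 205.4 ± 26.7 and 487.8 ± 46.4, and epicardial, glial, adipocyte and erythroid markers to 14.53 ± 1.75 and 72.26 ± 13.1. Acan was at least 46.5-fold lower, and Nppb, the B-type natriuretic peptide, at least 166-fold higher. DMSO with TGF-β1 against TGF-β1 alone gave 0 genes by edgeR, 988 at unadjusted p below 0.05 and 71 by DESeq2. Without TGF-β1 replicate 1, a library of low agreement, it gave 2670.

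**Figure D3:**
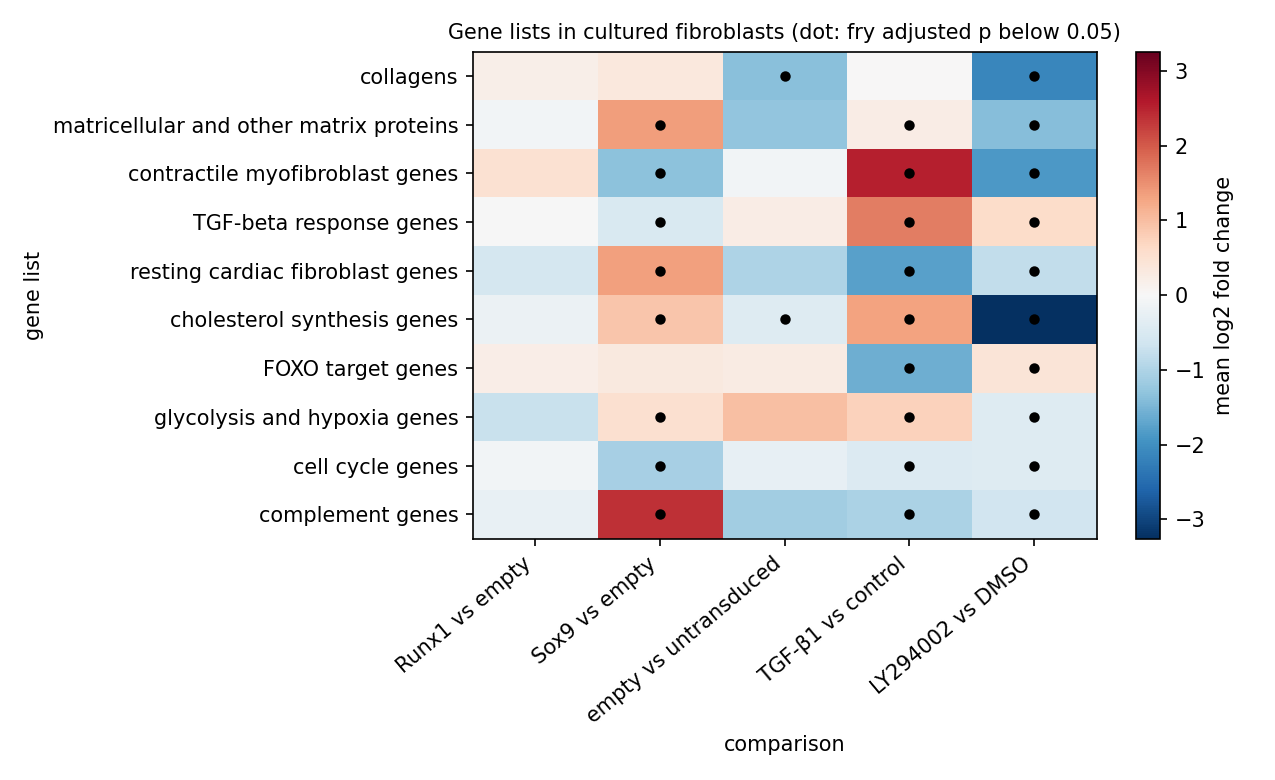
Mean log2 fold change of the tested members of 10 fixed gene lists (rows) in 5 comparisons of cultured cardiac fibroblasts (columns). Dots mark lists with a fry adjusted p below 0.05. Cholesterol synthesis genes were above 0 with TGF-β1 and below 0 with added LY294002.

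Cthrc1 knockout hearts were compared with wild type at day 5 in mEFSK4+ fibroblasts, CD31+ and CD45+ cells, to ask what the loss of this secreted matrix protein changes. The Cthrc1 transcript was not analysed here. In fibroblasts (n = 2 each) 0 genes passed by edgeR, with 432 at unadjusted p below 0.05 and 14 by DESeq2. With no filter the count was 39, and all cell types shared 1 estimate of spread. Of matrix genes singled out after their values were seen, Postn stood at 0.06 ± 0.52, Col1a2 at 0.19 ± 0.64 and Fn1 at -0.20 ± 0.27, each at adjusted p 1. No list moved on balance, collagens included (0 of 14 up and 0 down, 0 and 0 adjusted over the list alone, fry adjusted p 0.957), and cell cycle genes had a mean of -0.86 (0 of 19 up and 0 down, 0 and 4 adjusted over the list alone, fry adjusted p 0.483). In CD31+ cells 0 genes passed, with 1160 at unadjusted p below 0.05, 57 by DESeq2 and 249 with no filter. There oxidative phosphorylation genes moved down (0 of 12 up and 0 down, 0 and 1 adjusted over the list alone, fry adjusted p 0.0338). That call ended without knockout replicate 1 (adjusted p 0.17) or wild-type replicate 2 (0.224), with no filter, blocked on the replicate and in a fit of these groups alone. In CD45+ cells 0 passed, with 404 at unadjusted p below 0.05, 1 by DESeq2, 22 with no filter and 1 in a fit of these groups alone. Tests of whether the knockout effect differed between fibroblasts and CD31+ or CD45+ cells called 0 genes each by edgeR, with 573 and 426 at unadjusted p below 0.05 and 0 and 1 by DESeq2. With no filter they called 85 and 22. In data simulated for the fibroblast comparison, with 193 of 9962 genes changed, the test recovered 1.5% at 2-fold and 60% at 4-fold.

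The pig table gives Ensembl IDs without gene names, and no list was tested. Infarct against remote zone, within the same day, gave 3062 genes at day 8 (1681 up, 1381 down, n = 2 each), 8479 at day 60 (4549 up, 3930 down, n = 6) and 5893 at day 180 (3097 up, 2796 down, n = 9). ENSSSCG00000013916 rose by 11.32 ± 1.28 at day 60 and 7.80 ± 1.03 at day 180, and ENSSSCG00000001832 by 10.84 ± 1.10 and 6.84 ± 1.11. ENSSSCG00000035429 fell by 3.67 ± 0.39 and 3.22 ± 0.33. The infarct effect differed between day 180 and day 60 at 2481 genes (1438 more positive and 1043 more negative at day 180). Against healthy hearts (n = 4), the infarct zone gave 5027, 7878 and 2549 genes at days 8, 60 and 180 and the remote zone 563, 6320 and 1891. The day 60 libraries were deeper (8.32 M to 13.2 M against at most 5.29 M) and bear labels of another format, so day 60 and that batch cannot be separated in those comparisons or in the test between days. At day 8 the count against the remote zone was 734 without infarct replicate 2 and 1666 and 1353 without remote replicate 1 or 2. Against healthy hearts at day 8 the infarct zone gave 2485 without infarct replicate 2. The remote zone gave 34 and 325 without remote replicate 1 or 2, 349 without healthy replicate 4 and 322 in a fit of these groups alone. At day 180 the infarct zone gave 1699 without healthy replicate 2 and the remote zone 860 without healthy replicate 4.

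In human hearts with myocardial infarction the left ventricle was compared with healthy donors to set the animal response beside disease. CTHRC1 (ENSG00000164932, chromosome 8), the gene the series is named for, rose by 0.87 ± 0.32 (adjusted p 0.0476), from 1.14 ± 0.529 CPM in 6 healthy to 2.09 ± 0.79 CPM in 10 infarcted ventricles. That call ended with no filter (adjusted p 0.116), blocked on the replicate (0.0919) and in a fit of these groups alone (0.0634). ACE, which forms angiotensin II, rose by 3.42 ± 0.31 and APLNR, the apelin receptor of endothelium, by 3.39 ± 0.47. Angiogenic genes moved up (7 of 15 up and 0 down, 8 and 0 adjusted over the list alone, fry adjusted p 0.00107), as did endothelial markers (6 of 14 up and 2 down, 6 and 2 adjusted over the list alone, fry adjusted p 0.0129). Interferon-stimulated genes (8 of 18 up and 0 down, 8 and 0 adjusted over the list alone, fry adjusted p 0.0209) and class II antigen presentation genes (3 of 7 up and 0 down, 3 and 0 adjusted over the list alone, fry adjusted p 0.0221) moved up too. Of the collagens 11 of 16 tested genes rose, 0 fell and 5 did not pass (13 rose and 0 fell adjusted over the list alone), with COL1A1 at 5.86 ± 1.41. Its level was 1290 ± 3607 CPM with infarction and 22.2 ± 23.1 in healthy ventricles, so the rise was uneven, and without the infarction libraries that stood apart from their group it was 2.75 (adjusted p 4.2e-04). Fry did not call the collagens (adjusted p 0.0767) but did without those libraries (adjusted p 0.00239). Fibroblast markers summed to 4721 ± 9536 CPM with infarction and 1310 ± 167 in healthy ventricles. Reparative macrophage genes moved down (1 of 14 up and 4 down, 2 and 5 adjusted over the list alone, fry adjusted p 0.0129), with the macrophage receptor CD163 at -2.69 ± 0.32. VSIG4, a macrophage receptor not on that list, stood at -2.92 ± 0.45. The neutrophil gene S100A9 fell by 3.08 ± 0.50 in a lymphocyte and neutrophil list that did not pass (0 of 5 up and 2 down, 0 and 2 adjusted over the list alone, fry adjusted p 0.138) and had a median of 0.32 and a mean of -0.70. Cardiomyocyte markers did not move on balance (2 of 18 up and 0 down, 1 and 0 adjusted over the list alone, fry adjusted p 0.713), at 106500 ± 17180 CPM with infarction and 131300 ± 16440 in healthy ventricles. In the healthy ventricles 4 chromosome 21 genes took 17.96% ± 18.03 of counts, against 0.57% ± 1.02 with infarction. Mitochondrial genes took 4.8% ± 2.05 against 7.16% ± 2.74. MYH6 and MYH7 took 1.8% ± 0.75 against 4.92% ± 3.4, and TTN 8.77% ± 2.32 against 7.65% ± 2.66. Lymphocyte and neutrophil markers summed to 11.82 ± 4.99 CPM with infarction and 37.86 ± 24.5 in healthy ventricles, and epicardial, glial, adipocyte and erythroid markers to 101.5 ± 44 and 58.6 ± 33.9. The 6119 genes that passed (3642 up, 2477 down) became 11 with a term for the format of the labels, which all infarction libraries share with 1 healthy donor, so infarction and that batch are nearly confounded. The call on CTHRC1 ended with that term (0.46 ± 0.66, adjusted p 0.937). With the term the calls on each other gene and list named here that had passed ended too, in part at about the same size and a wider spread: ACE stood at 3.38 ± 0.73, APLNR at 3.31 ± 1.10, CD163 at -2.46 ± 0.53, VSIG4 at -2.28 ± 0.75, S100A9 at -2.27 ± 0.84 and COL1A1 at 4.24 ± 2.98. The mean went from 1.10 to 0.97 for angiogenic, from 0.52 to 0.49 for endothelial, from 0.82 to 1.27 for interferon-stimulated, from 0.70 to 1.35 for class II and from -0.34 to -0.34 for reparative macrophage genes. Those on endothelial, interferon-stimulated and class II genes also ended blocked on the replicate (adjusted p 0.0894 to 0.132). The count was 3727 in a fit of these groups alone and 1190 blocked on the replicate.

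In the right ventricle infarction gave 5884 genes (3510 up, 2374 down), and 60 with the label format term. CTHRC1 rose by 0.99 ± 0.32 (adjusted p 0.029), a call that ended with no filter, blocked on the replicate, with the term and in a fit of these groups alone (adjusted p 0.0543 to 0.846). FNDC1, a fibronectin domain protein, rose by 3.56 ± 0.37 and LTBP2, of the family that binds latent TGF-β, by 2.55 ± 0.47. Collagens moved up (11 of 16 up and 0 down, 12 and 0 adjusted over the list alone, fry adjusted p 0.0119). Oxidative phosphorylation genes moved down (0 of 21 up and 10 down, 1 and 13 adjusted over the list alone, fry adjusted p 0.00448), as did leukocyte markers (0 of 13 up and 5 down, 0 and 6 adjusted over the list alone, fry adjusted p 0.00448). Beside them mitochondrial genes took 6.95% ± 2.72 of counts with infarction and 4.52% ± 1.27 in healthy ventricles, and the 4 chromosome 21 genes 0.47% ± 0.66 and 14.15% ± 13.18. Lymphocyte and neutrophil markers summed to 15.52 ± 8.28 and 55.31 ± 33.7 CPM, and epicardial, glial, adipocyte and erythroid markers to 164.7 ± 112 and 59.93 ± 37.8. IL1RL1, the IL-33 receptor, stood at -4.30 ± 0.35. With the term the calls on FNDC1 (2.83 ± 0.79) and LTBP2 (2.25 ± 1.06) ended at a lower fold and a wider spread, and that on IL1RL1 did not (-4.52 ± 0.50, adjusted p 1.13e-04). The list calls ended too: the mean went from 1.37 to 1.02 for collagens, from -0.49 to -0.04 for oxidative phosphorylation genes and from -0.81 to -0.38 for leukocyte markers. A test of the infarction effect between left and right ventricles called 0 genes by edgeR and by DESeq2, with 158 at unadjusted p below 0.05.

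In dilated cardiomyopathy (n = 5) CTHRC1 stood at 1.00 ± 0.37 in the left (adjusted p 0.27) and 0.88 ± 0.36 in the right ventricle (adjusted p 0.264), short of the threshold. ACE rose by 2.38 ± 0.33 and 2.36 ± 0.29, and FNDC1 by 2.61 ± 0.31 and 2.48 ± 0.38. The Wnt antagonist SFRP4 rose by 4.07 ± 0.62 in the right ventricle (3.35 without 1 of the 5 libraries). CD163 stood at -2.27 ± 0.40 and -2.80 ± 0.53. Interferon-stimulated genes moved up in the left (3 of 18 up and 0 down, 10 and 0 adjusted over the list alone, fry adjusted p 0.00691) and right ventricle (6 of 18 up and 0 down, 11 and 0 adjusted over the list alone, fry adjusted p 0.00431). Leukocyte markers moved down in the right (0 of 13 up and 4 down, 0 and 8 adjusted over the list alone, fry adjusted p 0.0156), and fibroblast markers moved up in the left (2 of 13 up and 0 down, 4 and 0 adjusted over the list alone, fry adjusted p 0.0171). Beside these lists, lymphocyte and neutrophil markers summed to 7.964 ± 4.44 CPM with cardiomyopathy and 37.86 ± 24.5 in healthy left ventricles, and to 14.87 ± 11.8 and 55.31 ± 33.7 in right ones. Epicardial, glial, adipocyte and erythroid markers summed to 346.6 ± 536 and 58.6 ± 33.9 in the left and 320.2 ± 352 and 59.93 ± 37.8 in the right. In fits of these groups alone the 4 list calls ended (adjusted p 0.0583 to 0.0594). Except for that on interferon-stimulated genes of the left ventricle they also ended blocked on the replicate, and that on leukocyte markers without 1 of the 5 libraries (0.0584). The left ventricle gave 158 genes and the right 392. The left count lay between 33 and 138 without 1 of the 5 libraries, at 31 blocked on the replicate, 83 with no filter, 760 in a fit of these groups alone and 779 by DESeq2. The right count lay between 169 and 368 without 1 of the 5, at 140 blocked, 1053 by DESeq2 and 1289 in a fit of these groups alone. Between left and right ventricles over all donors 27 genes passed (12 higher and 15 lower on the left). The natriuretic peptide clearance receptor NPR3 stood at 1.11 ± 0.24 and GPD1, a glycerol phosphate dehydrogenase, at -1.43 ± 0.29. Ventricles of a donor paired, and a fit blocked on the donor gave 272. DESeq2 gave 92, 68 passed without the 3 infarction libraries that stood apart, and no list moved.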

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

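The tests of library size and of leukocytes in the infarct zone, of infarction libraries that stand apart and of a lower fibroblast share in Cd200+ cells were chosen only after the result was seen.

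Among 58 combinations of a group of 4 to 10 libraries and a measure, 10 had 1 library far from the others, where chance marks about 1 in 20 groups (2.9 expected). Total counts were 2.61 M (mega) in empty vector replicate 1, with 6.59 M to 8 M in the others. They were 50.3 M in 1 healthy left ventricle (others 15 M to 18.9 M), 4.78 M in 1 infarcted left ventricle (others 15.5 M to 18.5 M) and 31.7 M in 1 left ventricle with dilated cardiomyopathy (others 17.5 M to 21.2 M). The mean correlation with the rest of the group was 0.618 in empty vector replicate 1 (others 0.902 to 0.907), 0.784 in Runx1 replicate 5 (others 0.885 to 0.918) and 0.831 in TGF-β1 replicate 1 (others 0.931 to 0.941). It was 0.842 in healthy CD31+ replicate 3 (others 0.868 to 0.872) and 0.908 in healthy pig replicate 4 (others 0.95 to 0.951). Leukocyte markers summed to 655 CPM in replicate 1 of TGF-β1 with DMSO, and to 568 to 582 CPM in the others.

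The effect of the infarct zone in pig differed between day 180 and day 60 at 2481 genes, by a test of the difference itself. The 3 cardiomyocyte libraries of day 5, which no comparison used, held 77580 CPM of cardiomyocyte markers.

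GFP+ cells held more leukocyte transcripts in the infarct and border zones than in the remote zone. A difference in library size was argued against: the deepest infarct-zone library held 184 CPM of leukocyte markers, against at most 16.62 in the remote zone. Outside the fixed lists 46 genes stood at 200 CPM or more in CD45+ cells at day 7 and at most 5 CPM in healthy GFP+ cells, a choice that used no library of the zones. Of these, 76.1% (35) were higher in both infarct-zone than in both remote-zone libraries and 63% (29) were so in the border zone, where chance gives 16.7%. The median rise was 1.83% of the CD45+ level in the infarct zone (quartiles 1.26 to 3) and 0.47% in the border zone. Infarct libraries held 184 and 1869 CPM of markers, so these values are not ranked. Leukocytes carried into the sort may explain part of it, but the share lay between the bounds set (50% and 80%). Transcription in GFP+ cells was not tested and cannot be told apart.

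The left ventricle gave 6119 genes between infarction and health, and all infarction libraries share a label format with 1 healthy donor. Without the 4 chromosome 21 genes 6312 passed. Their uneven share (0.05% to 49.29% in healthy and 1.99% to 58.09% in cardiomyopathy left ventricles) has an open cause. Infarction libraries that stand apart were argued against (9121 without them). With a term for the label format 11 genes passed. The median log2 change of the 6119, signed by their call, went from 1.06 to 0.75 and its median SE from 0.31 to 0.62. The sign stayed in 5926 of them (96.8%). The calls ended because the estimates shrank on the whole and their spread grew, so infarction and a batch that follows the format cannot be told apart.

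Upk3b and some other mesothelial genes were higher in Cd200+ than in Cd200− cells. A gain of every other cell type at once was argued against: leukocyte markers summed to 18.41 ± 5.89 CPM in Cd200+ and 77.63 ± 30.8 in Cd200− cells. Pericyte and smooth muscle markers went the other way (154.5 ± 14.5 and 63.33 ± 1.89). Whether the share of fibroblasts was lower was not decided, because a gain of particular cell types need not raise leukocyte markers. A change in pericytes stays open. Of 10 mesothelial genes on a list written before this test, 80% (8) were higher in both Cd200+ libraries and 1 was lower in both, with a median log2 change of 2.38. Nkain4 (3.42, adjusted p 0.0199) and Anxa8 (2.40, adjusted p 0.0284) passed upwards and Aldh1a2 downwards (-1.62, adjusted p 0.0323), and the list was not tested as a group. Mesothelial cells inside the gate may account for the rises but not for the fall of Aldh1a2, a hypothesis from 2 libraries each. GFP+ fibroblasts that express these genes were not tested.

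Other splits of the libraries into groups of the same sizes tested if chance gives as many genes. For CD31+ cells at day 7 so few calls decide little (3 genes, highest other 1). Chance could be excluded, with only the real split as large, for GFP+ cells at day 7 (731, 440). It could be for Sox9 (2259, 353), TGF-β1 (3836, 245) and LY294002 (4418, 0). The same held in pig for infarct against remote zone at day 60 (8479, 5955) and day 180 (5893, 2538) and for the difference between these days (2481, 527). It held against healthy hearts for the infarct zone at day 60 (7878, 6048) and day 180 (2549, 1236) and for the remote zone at day 60 (6320, 3891) and day 180 (1891, 200). In human it held for infarction in the left (6119, 3098) and right ventricle (5884, 4461), and for dilated cardiomyopathy in the left (158, 1) and right (392, 45). Between ventricles it held too (27, 10), and among 100 splits that part the ventricles of each donor the highest other gave 0.

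Chance could not be excluded for GFP+ cells at day 14 (441 genes, with 2 of 35 splits as large). The other split, with 2172 genes, set libraries 1 and 2 of both groups against the rest, which points to a structure of the samples. The 8 splits that part all 4 pairs of replicate numbers (highest other 0) were too few to exclude chance. Blocked on the replicate, in a fit of all GFP+ groups, the count was 300. Nor could chance be excluded for Runx1 (225, 20 of 100, highest other 1069) or empty vector (190, 29 of 84, highest other 648). Where 0 genes passed by edgeR every split gives as many, so the splits decide nothing there: CD31+ cells at day 30 (35 of 35, highest other 897), DMSO (35 of 35, highest other 3623) and the difference in the infarction effect between ventricles (100 of 100, highest other 634). Splits with several times the real count point to a structure of the samples. The highest for CD31+ cells put healthy replicates 1 and 2 with day 30 replicates 3 and 4, and that for DMSO put TGF-β1 replicate 1 with 3 DMSO libraries.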

How the results depend on the processing

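The library set, low agreement, Sox9 library and chromosome 21 alternatives were chosen after the data were seen. Among changes simulated at 2-fold, edgeR recovered 32.8% in GFP+ cells at day 7, 11.9% with Sox9, 1.5% in knockout fibroblasts and 0% in CD45+ cells at day 7. RLE scaling left 40 of 40 counts within 1.5 times. Of the 40 counts, 14 stayed within 1.5 times under every alternative fixed in advance that keeps the libraries, and 26 moved under at least 1 of them. By setting, the counts that moved were 21 of 40 with DESeq2, 15 of 40 with no filter, 12 of 38 with a replicate block, 1 of 2 with a donor block, 13 of 33 in a fit of the 2 groups alone, 2 of 2 with the label format term and 72 of 172 with a library left out. For the added settings they were 3 of 3 with the library set term, 4 of 9 without libraries of low agreement, 0 of 1 without Sox9 replicates 1, 3 and 4 (1549 against 2259 genes, with the 9 genes and 9 lists tested unchanged in call) and 0 of 4 without the chromosome 21 genes. Healthy donors of the same label format moved 0 of 2. Of the named genes and lists that had passed, 1 changed sign: the mean of FOXO targets in CD45+ cells at day 7 went from -0.53 to 0.09 without healthy replicate 1 (adjusted p 0.0947). Of those that had not passed, 9 did. Where 1 library remained in a group it was assumed to vary like the other groups.

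The values that moved follow, with the reported count in parentheses, and the cause was not tested. DESeq2 gave 1269 for GFP+ day 7 (731), 867 for GFP+ day 14 (441), 273 for GFP+ day 30 (76), 113 for CD31+ day 7 (3), 837 for CD31+ day 14 (279) and 11 for CD31+ day 30 (0). It also gave 92 for CD45+ day 7 (1), 11 for CD45+ day 14 (0), 18 for CD45+ day 30 (0), 9 for dermal (0), 316 for Cd200 (69) and 112 for Runx1 (225). Its other counts were 434 for empty vector (190), 71 for DMSO (0), 14 for knockout fibroblasts (0), 57 for knockout CD31+ (0), 1 for knockout CD45+ (0) and 779 for left ventricle cardiomyopathy (158). Further counts were 1053 for right ventricle cardiomyopathy (392), 92 for left against right ventricle (27) and 1 for knockout fibroblasts minus CD45+ (0). With no filter on low counts the numbers were 80 for CD31+ day 7 (3), 9 for CD31+ day 30 (0), 117 for CD45+ day 7 (1), 17 for CD45+ day 14 (0), 127 for CD45+ day 30 (0) and 56 for dermal (0). Others were 412 for Cd200 (69), 387 for Runx1 (225), 71 for empty vector (190), 39 for knockout fibroblasts (0), 249 for knockout CD31+ (0) and 22 for knockout CD45+ (0). Further ones were 83 for left ventricle cardiomyopathy (158), 85 for knockout fibroblasts minus CD31+ (0) and 22 for knockout fibroblasts minus CD45+ (0). Blocked on the replicate the counts were 30 for GFP+ day 30 (76), 0 for CD31+ day 7 (3), 54 for CD31+ day 14 (279), 25 for CD45+ day 7 (1), 3 for CD45+ day 30 (0) and 11 for dermal (0). The others were 729 for Cd200 (69), 12 for Runx1 (225), 25 for empty vector (190), 1190 for left ventricle infarction (6119), 31 for left ventricle cardiomyopathy (158) and 140 for right ventricle cardiomyopathy (392). Blocked on the donor the count was 272 for left against right ventricle (27). In a fit of the 2 compared groups alone they were 409 for GFP+ day 7 (731), 224 for GFP+ day 14 (441), 19 for CD31+ day 7 (3), 143 for CD31+ day 14 (279), 0 for CD45+ day 7 (1) and 760 for infarct zone (478). The remaining ones were 42 for Runx1 (225), 557 for empty vector (190), 1 for knockout CD45+ (0), 322 for pig day 8 remote against healthy (563), 3727 for left ventricle infarction (6119) and 760 for left ventricle cardiomyopathy (158). Then came 1289 for right ventricle cardiomyopathy (392). With a term for label format they were 11 for left (6119) and 60 for right ventricle infarction (5884). With a term for library set they were 1762 for GFP+ day 7 (731), 1311 for GFP+ day 14 (441) and 396 for GFP+ day 30 (76). Without libraries of low agreement they were 52 for Runx1 (225), 581 for empty vector (190), 2670 for DMSO (0) and 68 for left against right ventricle (27).

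With each library left out in turn, in groups of 2 to 5, counts ran from 178 to 846 for GFP+ day 7, 245 to 504 for GFP+ day 14, 19 to 84 for GFP+ day 30, 0 to 2 for CD31+ day 7, 25 to 407 for CD31+ day 14 and 0 for CD31+ day 30. They ran from 0 to 2 for CD45+ day 7, 0 to 2 for CD45+ day 14, 0 for CD45+ day 30, 8 to 5237 for dermal, 189 to 294 for infarct zone and 131 to 580 for border zone. The range was 145 to 696 for Cd200, 44 to 109 for empty vector, 3314 to 4817 for TGF-β1, 3957 to 4314 for LY294002, 0 to 2670 for DMSO and 0 to 2 for knockout fibroblasts. Ranges were 0 to 21 for knockout CD31+, 0 for knockout CD45+, 734 to 2402 for pig day 8 infarct against remote, 2485 to 4892 for pig day 8 infarct against healthy, 7159 to 7505 for pig day 60 infarct against healthy and 1699 to 2363 for pig day 180 infarct against healthy. Further ranges were 34 to 472 for pig day 8 remote against healthy, 5164 to 5835 for pig day 60 remote against healthy, 860 to 1553 for pig day 180 remote against healthy, 33 to 138 for left ventricle cardiomyopathy, 169 to 368 for right ventricle cardiomyopathy and 0 to 1 for knockout fibroblasts minus CD31+. The last were 0 to 2 for knockout fibroblasts minus CD45+.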

Other observations

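The Wt1 values below were singled out only after the results were seen, from comparisons fixed before. The 3 cardiomyocyte libraries of day 5 are given as values. Cardiomyocyte markers summed to 77580 ± 3262 CPM, with Myh6 (α-myosin heavy chain) at 10290 ± 2478, Myh7 at 2518 ± 776, Tpm1 at 13370 ± 954 and the mitochondrial carrier Slc25a4 at 16550 ± 675. The stress peptides Nppa and Nppb stood at 1977 ± 1040 and 468 ± 33.1 and skeletal actin Acta1 at 922 ± 234. Fibroblast markers summed to 980.3 ± 115 CPM, collagens to 791.1 ± 89.6, leukocyte markers to 198.8 ± 28.4 and endothelial markers to 265 ± 61.3. Postn stood at 95.2 ± 47.3. The most abundant genes were Gm29216 (101000 CPM), Gm28437 (99380) and Gm28661 (62950), which lowers other CPM.

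Wt1, the epicardial transcription factor named above at day 7, stood at 4.34 ± 1.01 at day 14 in GFP+ cells (adjusted p 0.0255). In GFP+ cells of the zones at day 7 it was at 2.40 ± 0.62 in the infarct zone (adjusted p 0.0262) and -2.83 ± 0.74 in the border zone (adjusted p 0.0361), both against the remote zone (n = 2 each). Its level was 39.6 ± 8.69 CPM in the infarct, 1.05 ± 1.49 in the border and 7.65 ± 1.79 in the remote zone. Calls on it ended by DESeq2 in both zones (adjusted p 0.474 and 0.374). In the infarct zone they also ended without infarct replicate 1 (0.0852) or 2 (0.39) or remote replicate 2 (0.0586). In the border zone they ended without border replicate 1 (-1.86, 0.0728, while without replicate 2 the border zone had 0 counts) or remote replicate 1 (0.0504) and in a fit of these groups alone (0.2). At day 14 the call ended blocked on the replicate (0.0512), without any 1 healthy replicate (0.0559 to 0.0771) and without day 14 replicate 3 (0.0678). Infarct and border zones were not compared with each other.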
